A study of Brassica juncea with 21 samples.

How the data were processed

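RNA sequencing libraries were made by the authors from leaves and from hand-dissected lateral and median floral nectaries of Brassica juncea at the pre-secretory, secretory and post-secretory stages. Per the labels there were 21 libraries, 3 in each of 7 groups. Plants were about 40 days old and grown at 21 °C with 16 h of light at 200 µmol and 8 h of darkness. Each nectary RNA sample held about 100 nectaries, at most 4 from 1 flower, and replicates came from different sets of plants. The labels place nectary dissection on several days between 4 and 8 h after dawn, and the post-secretory stage 12 h after the secretory one, so the time of day of the pre-secretory and post-secretory samples is not settled by them. TruSeq RNA v2 libraries were sequenced on an Illumina HiSeq instrument with 50 bp paired-end reads in 2 lanes, with at least 162 M reads stated for the pool. Depth per library is not given in the sources used here.

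The deposited table holds 1 score per group and transcript, a normalized expression value rounded to a whole number. Per the file headers the columns are marked UQN, which was read as upper-quartile normalized, although the abbreviation is not spelled out. The lateral post-secretory column lacks this mark and was taken to hold the same score. Its 75th percentile, 476, lay within those of the other 6, from 450 to 543.75. It also had the lowest total (7081592), the highest median (192), the lowest maximum (51947) and the fewest transcripts at 0 (48). That it holds the same score was not tested, and every comparison with this column rests on it. The aligner, the counting method, the way in which 3 libraries became 1 value and any filter the authors applied are not given in the sources used here. Each line of the table is a Brassica rapa transcript that Brassica juncea sequence matched. There were 14398 transcripts of 13904 genes, 9605 with an Arabidopsis match, 4793 (33.3%) without one and 280 matched to over 1 Arabidopsis locus. Gene symbols are those of the matched Arabidopsis locus or of the product name. Copies in the polyploid Brassica juncea genome that match the same Brassica rapa transcript were not separated.

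Because each group had 1 value, no statistical test, no p-value, no interval and no measure of replicate spread was computed. The comparisons, gene lists, rule for named genes and alternatives had been written before the data were examined, for counts per library, with differences of group values set down as the fallback. Transcripts with a value of at least 1 in at least 3 groups were kept, 14390 in all, and 8 were left out. Differences were taken on log2 of the value plus a pseudocount of 1, and a difference of 2-fold or more was counted as higher or lower. Where a group was listed at 0, its values are given without a fold.

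There were 11 comparisons. Secretory nectaries were compared with leaf as the mean log2 value of the 2 nectary types minus leaf. Within each nectary type the secretory stage was compared with the pre-secretory stage and the post-secretory stage with the secretory stage. Both steps use the same secretory value, so opposite differences in the 2 steps are not independent. Lateral nectaries were compared with median nectaries at each of the 3 stages and as the mean over stages. For each of the 2 stage steps the lateral difference minus the median difference was taken. Agreement between nectary types was described by Pearson's r across transcripts and by the number of transcripts past 2-fold in both, beside the number expected if the types were independent.

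Genes were grouped by 20 lists of Arabidopsis loci written from general knowledge: nectary and nectar genes, sugar transport and sucrose cleavage, starch synthesis, starch breakdown, photosynthesis, floral organ identity, jasmonate, auxin, gibberellin, circadian clock, cell division, senescence and sugar starvation, glucosinolates and myrosinases, terpene synthases, handling stress, guard cell lineage, and markers of pollen, tapetum, carpel and ovule, and vascular tissue. Transcripts joined a list by locus or by a symbol ending the product name. For lists with at least 3 measured transcripts, the median log2 difference was placed among 10000 random lists of the same size matched on mean value in 20 bins, with a fixed seed. The percentile describes the list and is not a test, since transcripts within a list are not independent, and about 5 in 100 lists fall outside percentiles 2.5 to 97.5 by construction.

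Named genes followed a rule. It took the 5 largest differences each way with a value of at least 10 in the higher group and an Arabidopsis match or a gene name. It also took up to 4 members per list. In the stage, type and leaf comparisons it added CRC, SWEET9, CWINV4, MYB21, MYB24, PIN6, JMT and GA2OX6. In the stage comparisons it added the clock genes CCA1, LHY and TOC1. The copy with the largest mean was named. The parts of the rule that relied on adjusted p-values and on replicates not overlapping were replaced by the size of the difference. The report names part of the genes and list members that the rule selects.

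The counting and the random lists were tested on simulated data for the lateral secretory against pre-secretory comparison. Both columns were redrawn by Poisson sampling around the pre-secretory values. Of 40 transcripts made 3-fold higher, 39 were past 2-fold, and of 40 made 3-fold lower, 36 were. None of 40 made 1.5-fold higher was (0), and of 14190 left alone, 263 were. Of 200 random lists, 5 left alone lay outside the 95% range, and all 200 lay above it once their medians were raised 3-fold. Such draws hold counting error only, with no spread between libraries and no dependence between transcripts. The 263 and the 5 are therefore not error rates for the deposited values.

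Alternatives computed were pseudocounts of 0.1 and 10, no filter on low values, a value of at least 50 in at least 1 group, quantile normalization between columns, columns scaled to the same total, 1 transcript per gene, the most highly expressed copy per locus, and list members taken by locus only. The pseudocount of 10, the filter at 50, the same-total scaling, 1 transcript per gene and locus-only members were chosen after the data were seen. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not realigned, and values per library were not used here.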

Results

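Transcript levels were measured by RNA sequencing in the floral nectaries and the leaves of Brassica juncea, a mustard whose flowers carry 2 types of nectary, lateral and median. Each nectary type was sampled at 3 stages. Pre-secretory nectaries were taken 24 h before anthesis, secretory nectaries at full anthesis, from 4 to 8 h after dawn, and post-secretory nectaries 12 h after the secretory stage. Leaf was collected when secretory nectaries were. The 7 groups held 3 libraries each, 21 in all, and each nectary library came from about 100 hand-dissected nectaries pooled from separate sets of plants.

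The table analysed here gives 1 normalized whole-number value per group for each of 14398 transcripts, named by their Brassica rapa match, and 14390 were kept. There was therefore no replicate spread, no test and no p-value for any comparison, and "higher" and "lower" below refer to group values alone. Column totals ran from 7081592 in lateral post-secretory nectaries to 11197495 in median secretory nectaries, column medians from 168 to 192, and 48 to 163 transcripts per column were listed at 0. A single transcript described as an F-box/kelch-repeat protein (LOC103828338) held 13.2% of the median secretory column. The read depth per library is unknown, since the study states at least 162 M reads only for the pool.

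The comparison of secretory nectaries with leaf addressed which transcripts differ between nectar-secreting tissue and leaf. Leaf was the only other tissue, so the comparison does not separate secretion from floral origin. The nectary and nectar genes stood furthest apart: 18 of 19 measured transcripts were at least 2-fold higher in secretory nectaries and 1 was lower, with a median log2 difference of 8.13, above all 10000 random lists. SWEET9 (LOC103857843), the transporter that exports sucrose from nectary cells, was listed at 147160 in lateral and 23865 in median secretory nectaries and at 19 in leaf, a log2 difference of 11.53. CWINV4 (LOC103865521), a cell wall invertase that cleaves exported sucrose, was listed at 147338, 77852 and 67 in the same order (log2 10.62). CRC (LOC103831319), a YABBY transcription factor required to form nectaries in Arabidopsis, was 470-fold higher than in leaf. MYB57 (LOC103870993) and MYB21 (LOC103875192), a pair of jasmonate-regulated floral MYB factors, had log2 differences of 10.28 and 9.45. JMT (LOC103872765), which methylates jasmonic acid, and PIN6 (LOC103832163), an auxin carrier, had differences of 8.12 and 7.42. The other copies of SWEET9, CWINV4, MYB21 and JMT lay between 5.56 and 9.45. SPS4F (LOC103853568), a sucrose phosphate synthase, was the lower member, at 48 and 210 against 1908 in leaf. MYB24 and GA2OX6 were not analysed here.

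The Arabidopsis gene models matched to these transcripts have positions in the table, with no build named. SWEET9 lies on chromosome 2 from 16306818 to 16308206, CWINV4 on chromosome 2 from 15174951 to 15177785 and CRC on chromosome 1 from 26007734 to 26008940, all 3 on the reverse strand. PIN6 lies on chromosome 1 from 28970855 to 28974224, forward strand. Which parts of each gene these spans cover is not stated, so exons and untranslated regions were not resolved.

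**Figure D1:**
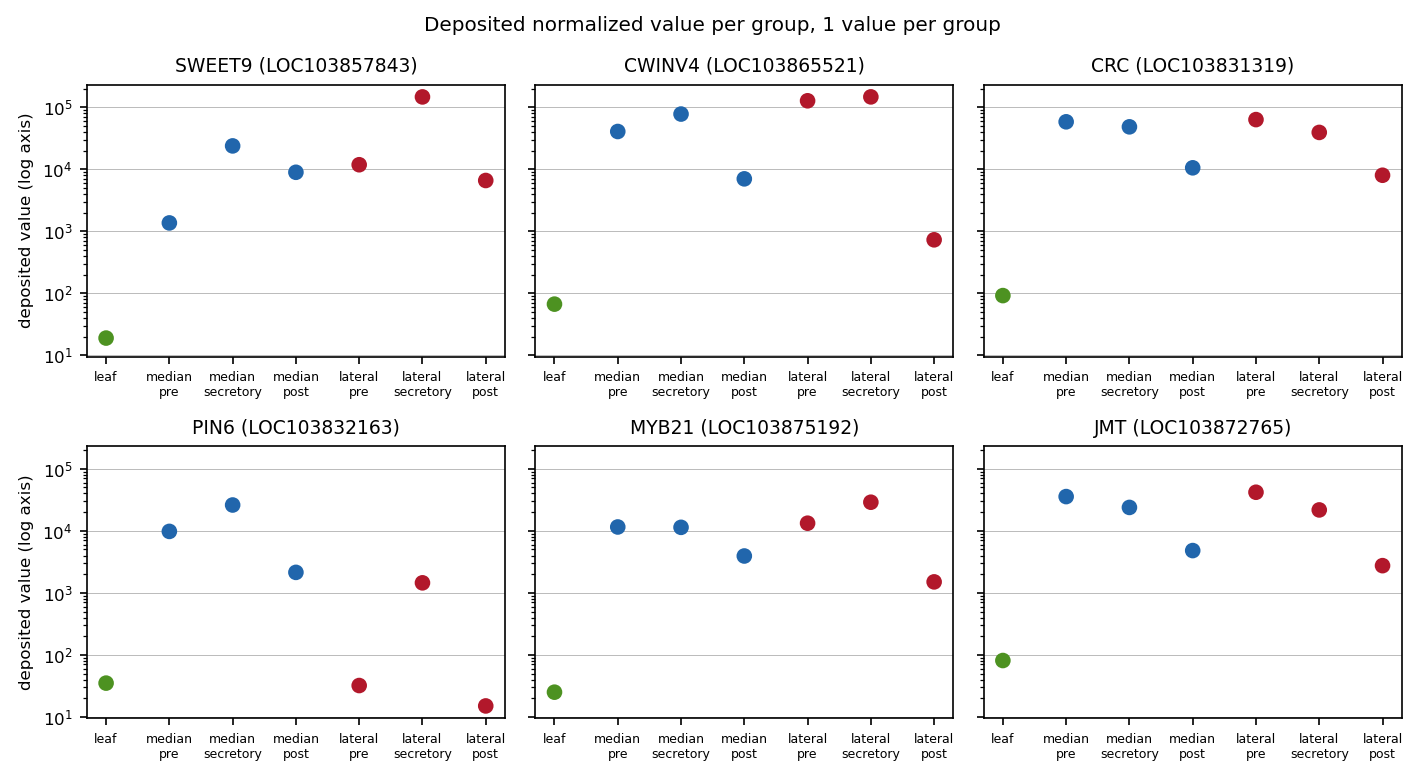
Deposited normalized value (log axis) of SWEET9, CWINV4, CRC, PIN6, MYB21 and JMT in leaf (green), median nectaries (blue) and lateral nectaries (red) at 3 stages, 1 point per group and no error bars. Leaf values lie between 19 and 92, and SWEET9 is highest in lateral secretory nectaries at 147160.

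Floral organ identity transcripts were also higher than in leaf, 9 of 11 by at least 2-fold with a median of 4.98. SHP2 (LOC103866661) was listed at 25226 in lateral and 29798 in median nectaries against 33, and SEP1 (LOC103846385), SHP1 (LOC103830183) and AP3 (LOC103863238) had log2 differences of 7.66, 7.29 and 6.64. The 2 members within 2-fold were copies of LUG. All 27 photosynthesis transcripts were lower in secretory nectaries, with a median of −3.16. LHCB1.3 (LOC103865334), a light-harvesting protein, was listed at 521766 in leaf and at 24330 and 28516 in lateral and median nectaries. BCA1 (LOC103870985), a chloroplast carbonic anhydrase, was listed at 45925 in leaf and at 1 and 30, a difference of −12.51, and RCA (LOC103865740), Rubisco activase, had a difference of −5.71.

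Sugar and starch lists were mixed against leaf. Of 19 sugar transport and sucrose cleavage transcripts, 7 were higher and 9 lower (median 0.78, percentile 94.0, and −0.14 with the most expressed copy per locus alone). The sucrose synthase SUS1 (LOC103845641) was 165-fold higher, and SWEET5 (LOC103855024) was listed at 2169 and 734 in lateral and median nectaries and at 0 in leaf. The vacuolar invertase VI2 (LOC103843145) had a difference of −6.41. Starch synthesis had 1 of 9 members higher and 4 lower (median −0.78, percentile 5.62), with the pyrophosphorylase subunit APL1 (LOC103845771) at −7.70. Starch breakdown had 4 of 14 higher and 7 lower (median −0.76, percentile 2.84), with the beta-amylases BAM1 (LOC103828653) at 2.00 and BAM3 (LOC103860895) at −4.25. With the most expressed copy per locus alone the 2 starch medians were −1.64 and −1.24.

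Among the hormone lists, 12 of 21 jasmonate transcripts were higher than in leaf and 3 lower (median 1.40, percentile 99.9). The transcript labelled OPCL1 here (LOC103835792) matched that jasmonate-synthesis locus and 1 other locus, and its product name is 4-coumarate--CoA ligase-like 8. Which of these loci it corresponds to is not settled. It had a difference of 9.22, JAZ10 (LOC103846592) of 8.18 and MYC2 (LOC103874758) of −1.31. Auxin transport and response had 2 of 7 higher and 2 lower (median 0.54, percentile 70.6), with ARF6 (LOC103840407) at 2.18 and PIN3 (LOC103830868) at −3.32. The 2 gibberellin transcripts differed in direction, with GID1A (LOC103870853) at 1.26 and GASA4 (LOC103856125) at −2.96. Of the glucosinolate and myrosinase list, 3 of 4 members were lower (median −4.99). CYP83A1 (LOC103863599), an enzyme of glucosinolate synthesis, was listed at 1720 in leaf and at 1 and 0 in nectaries.

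Cell division transcripts were higher in 6 of 7 cases (median 1.71, percentile 98.9), with the cyclin-dependent kinase CDKB2;1 (LOC103832116) at 4.11. These values average nectary types that differed at secretion. Lateral against median secretory nectaries gave this list a median of −3.48 (−1.53 by locus alone), with CDKB2;1 going the other way. The difference from leaf is therefore not one that both types share equally. Senescence had 0 of 7 higher and 4 lower (median −1.59, percentile 3.54, and −1.03 with the most expressed copies), with the NAC factor NAP (LOC103831344) at −6.77. The clock list had 5 of 13 higher and 1 lower (median −0.30, percentile 14.6), PRR5 (LOC103874318) at 4.85 and CCA1 (LOC103866427) at −1.12. The terpene synthase TPS03 (LOC103833974) was 8.69-fold higher, the only measured member of its list. Stress-response transcripts used as a sign of handling were higher in 4 of 7 and lower in 1 (median 1.2, percentile 96.4, and 0.99 with same-total scaling). All 4 pollen marker transcripts were higher than in leaf (median 4.47), among them the calcium pump ACA9 (LOC103859893) at 5.95. The 2 guard cell transcripts, both KAT1, were higher. The vascular list had 2 of 6 higher and 4 lower with a median of −1.61, which was 2.12 when the 3 members assigned by product name alone were left out, an alternative chosen after the data were seen. No transcript of the tapetum list or of the carpel and ovule list was measured (0 of each).

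In total, 3828 transcripts were at least 2-fold higher in secretory nectaries than in leaf and 3661 were lower, of 14390 compared. Besides SWEET9 and CWINV4, the largest differences upward were in the lipid-binding protein AIR1B (LOC103858045), at 27894 and 7320 against 7, and in uncharacterized LOC103841920 and LOC103834478, each listed at 1 in leaf. Downward, besides BCA1, they were a glycine-rich protein 3 isoform (LOC103860335), at 0 and 4 against 6389, gibberellin-regulated protein 6 (LOC103852917), at 0 and 1 against 3620, the proline-rich protein DC2.15-like (LOC103848198), at 0 and 2 against 3991, and a carbonic anhydrase 1-like transcript (LOC103850064), at 0 in both against 3131.

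The stage comparisons asked which transcripts differed as nectaries went from before secretion, through secretion, to after it. In lateral nectaries, SWEET9 was 12.4-fold higher at the secretory than at the pre-secretory stage (147160 against 11858), MYB57 159-fold higher (5559 against 34) and PIN6 44.0-fold higher (1450 against 32). Of the 19 nectary and nectar transcripts, 10 were higher and 2 lower (median 1.04, percentile 99.7). CRC (log2 −0.69) and JMT (−0.95) were lower by less than 2-fold, while the other JMT copies, LOC103829478 and LOC103835835, had 2.11 and 0.67. CWINV4 had a difference of 0.21, its other copy (LOC103857608) one of −1.2, and MYB21 was 2.18-fold higher (log2 1.12), its other copy 1.16-fold lower. After quantile normalization CRC had −1.76, JMT −1.91, CWINV4 −2.08, MYB21 0.30 and the list median 0.30, so the calls of these 4 genes depend on the normalization. CWINV4 held the highest value of the lateral pre-secretory column (127450). Quantile normalization replaces it by the mean of the 7 column maxima, 1 of them 1477508, so the −2.08 partly reflects that replacement. With same-total scaling CRC had −1.18, JMT −1.44, MYB21 0.63 and the list 0.55.

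Carbohydrate transcripts also differed between these lateral stages. Of 19 sugar transport and sucrose cleavage transcripts 12 were higher and 3 lower (median 1.00, percentile 99.3, and 0.58 with a pseudocount of 10 or 1.85 with one of 0.1). SUS1 was listed at 18364 before and 123226 at secretion, and the phloem sucrose transporter SUC2 (LOC103840834) at 57 and 376. VI2 was lower, at 91 and 7. None of the 9 starch synthesis transcripts was higher and 5 were lower (0 and 5, median −2.13, percentile 0.01), with APL2 (LOC103839024) at 628 before and 62 at secretion and SS2 (LOC103870956) at 491 and 92. Starch breakdown had 3 of 14 higher and 6 lower (median −0.67, percentile 5.24), a median of −1.02 with the most expressed copy per locus alone and −1.15 with same-total scaling. BAM1 was 19.9-fold higher (32351 against 1628), and the alpha-amylase AMY3 (LOC103831524) was 12.7-fold lower.

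Cell division transcripts were lower in 5 of 7 cases at the lateral secretory stage (median −3.89, below all random lists, and −1.45 without the 3 members assigned by product name alone). The replication licensing subunits MCM2 (LOC103849416), MCM5 (LOC103860343) and MCM7 (LOC103858780) were 21.0-, 15.2- and 14.9-fold lower, while CDKB2;1 was 19.3-fold higher. Of 21 jasmonate transcripts, 3 were higher and 12 lower (median −1.29). LOX2 (LOC103830993), a lipoxygenase of jasmonate synthesis, was listed at 38280 before and 2487 at secretion, VSP1 (LOC103854787) at 1894 and 177, and the peroxisomal oxidase ACX1 (LOC103869185) was 4.1-fold higher. Clock transcripts were higher in 7 of 13 cases and lower in 2 (median 1.73, or 1.13 after quantile normalization), with PRR9 (LOC103866432) 39-fold higher, CCA1 10.8-fold, LHY (LOC103844616) 3.33-fold and GI (LOC103249166) 2.70-fold lower. The other copy of LHY was 7.53-fold higher, and TOC1 was not analysed here.

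Stress-response and pollen transcripts differed along with these lists. Stress-response transcripts were higher in 6 of 7 cases (median 4.84), with the zinc finger factor ZAT12 (LOC103845403) at 12 before and 725 at secretion and HSP17.6 (LOC103249161) at 10 and 534. This list was meant as a sign of handling, and it was also higher in median secretory nectaries (below). Whether handling differed between the stages was not tested, so handling and stage cannot be told apart in this step. All 4 pollen markers were higher (median 2.34, percentile 99.8), with ACA9 at 250 and 2324. In the other lists the split was 2 higher and 0 lower of 27 for photosynthesis (median 0.18), 4 and 2 of 11 for floral organ identity (−0.26), 1 and 2 of 7 for auxin (−0.08), 1 and 1 of 7 for senescence (0.00), 0 and 3 of 4 for glucosinolates (−1.25, percentile 5.73) and 3 and 0 of 6 for vascular markers (1.3, percentile 96.1). The vascular median was 0.61 with the most expressed copy per locus alone, 0.83 with same-total scaling, 0.88 with a pseudocount of 10 and 2.44 by locus alone. TPS03 was 41.3-fold higher, GID1A 2.87-fold higher, GASA4 3.77-fold lower and both KAT1 transcripts lower.

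Across all transcripts, 3094 were higher and 3386 lower in lateral secretory than in lateral pre-secretory nectaries. With every column scaled to the same total, an alternative chosen after the data were seen, the split was 2024 and 5111 and the median of all transcripts was −0.528 in place of −0.04. The largest differences upward were in the cytochrome P450 78A9 (LOC103842009), at 2 and 3407, the calcium-binding CML38-like transcript (LOC103830603), at 1 and 1753, oleosin S2-2 (LOC103837001), at 2 and 2361, a rhodanese-like protein (LOC103849564), at 2 and 1840, and uncharacterized LOC103857045, at 4 and 2887. Downward, they were in uncharacterized LOC103831738, at 1703 and 1, the myrosinase-binding transcripts LOC103840046, at 1179 and 1, and LOC103867053, at 4667 and 8, and the GDSL lipases LOC103871089, at 958 and 1, and LOC103839650, at 857 and 1.

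In median nectaries the secretory stage again had higher SWEET9, 17.4-fold (23865 against 1367), MYB57, 11.2-fold, and PIN6, 2.66-fold. Of the 19 nectary and nectar transcripts, 9 were higher and 1 lower (median 0.93, percentile 99.9, and 0.36 after quantile normalization or 1.1 with the most expressed copies). CWINV4 (log2 0.93), CRC (−0.27), JMT (−0.58) and MYB21 (−0.02) lay within 2-fold, but the MYB21 copy LOC103837005 had −1.95 and the JMT copy LOC103829478 had 1.3. After quantile normalization JMT had −1.06 and PIN6 0.85. The sugar transport and sucrose cleavage list had 13 of 19 higher and 2 lower (median 1.90, above all random lists), with the sucrose transporter SUC1 (LOC103830824) at 3 before and 254 at secretion and SWEET15 (LOC103850848) at 4 and 264. Starch synthesis had 1 of 9 higher and 4 lower (median −0.80, percentile 1.72, and −1.21 with same-total scaling), with APL1 12.3-fold and APL2 7.32-fold lower. Starch breakdown had 2 of 14 higher and 5 lower (−0.26), with the phosphorylase PHS1 (LOC103875081) 55.2-fold lower.

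Jasmonate transcripts were lower in 14 of 21 median cases and higher in 1 (median −1.21). VSP1 was 14.5-fold, LOX2 12.1-fold and the reductase OPR3 (LOC103860353) 10.1-fold lower. Clock transcripts were higher in 7 of 13 cases and lower in 0 (median 1.54), with CDF1 (LOC103855006) 28.5-fold, PRR9 18.1-fold, CCA1 4.83-fold and LHY 4.47-fold higher. Stress-response transcripts were higher in 6 of 7 cases (median 3.35), with HSP17.6 65.6-fold and ZAT12 44.0-fold higher, and all 4 pollen markers were higher (median 3.05), AGP6 (LOC103858897) by 11.5-fold and VGD1 (LOC103858231) by 8.71-fold. Cell division had 1 of 7 higher and 0 lower (−0.01), photosynthesis 1 and 1 of 27 (0.15), floral organ identity 3 and 3 of 11 (−0.06), auxin 1 and 1 of 7 (−0.59, or −1.0 with same-total scaling), senescence 3 and 0 of 7 (0.55), glucosinolates 0 and 3 of 4 (−1.48, percentile 2.43, and −0.88 with a pseudocount of 10 or −2.73 with one of 0.1) and vascular markers 4 and 0 of 6 (1.48, percentile 98.7, and 0.46 with a pseudocount of 10). TPS03 was 32.7-fold higher, GASA4 9.82-fold lower and KAT1 (LOC103827743) 4.05-fold lower.

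Across all transcripts, 2532 were higher and 2641 lower in median secretory than in median pre-secretory nectaries. With columns scaled to the same total the split was 1752 and 3873 and the overall median −0.375 in place of 0.027. The largest differences upward were in a mitochondrial small heat shock protein (LOC103862989), at 0 and 932, an O-acyltransferase WSD1-like transcript (LOC103857833), at 17 and 9971, a class I small heat shock protein (LOC103851557), at 0 and 462, oleosin S2-2, at 0 and 439, and a RING finger protein (LOC103862903), at 0 and 410. Downward, they were in the aspartic proteases LOC103847097, at 1548 and 0, and LOC103841353, at 3532 and 6, the lipase LOC103839650, at 1189 and 0, an abscisate beta-glucosidase (LOC103868505), at 2414 and 3, and chlorophyllase-1 (LOC103872768), at 2830 and 4.

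The lateral and median nectaries gave similar differences between pre-secretory and secretory stages. Across transcripts, which are not independent replicates, Pearson's r between the log2 differences of the 2 nectary types was 0.824. At least 2-fold higher in both were 1926 transcripts, against 544.4 if the types were independent, and lower in both were 2088, against 621.4. Only 76 differed by 2-fold or more in opposite directions.

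**Figure D2:**
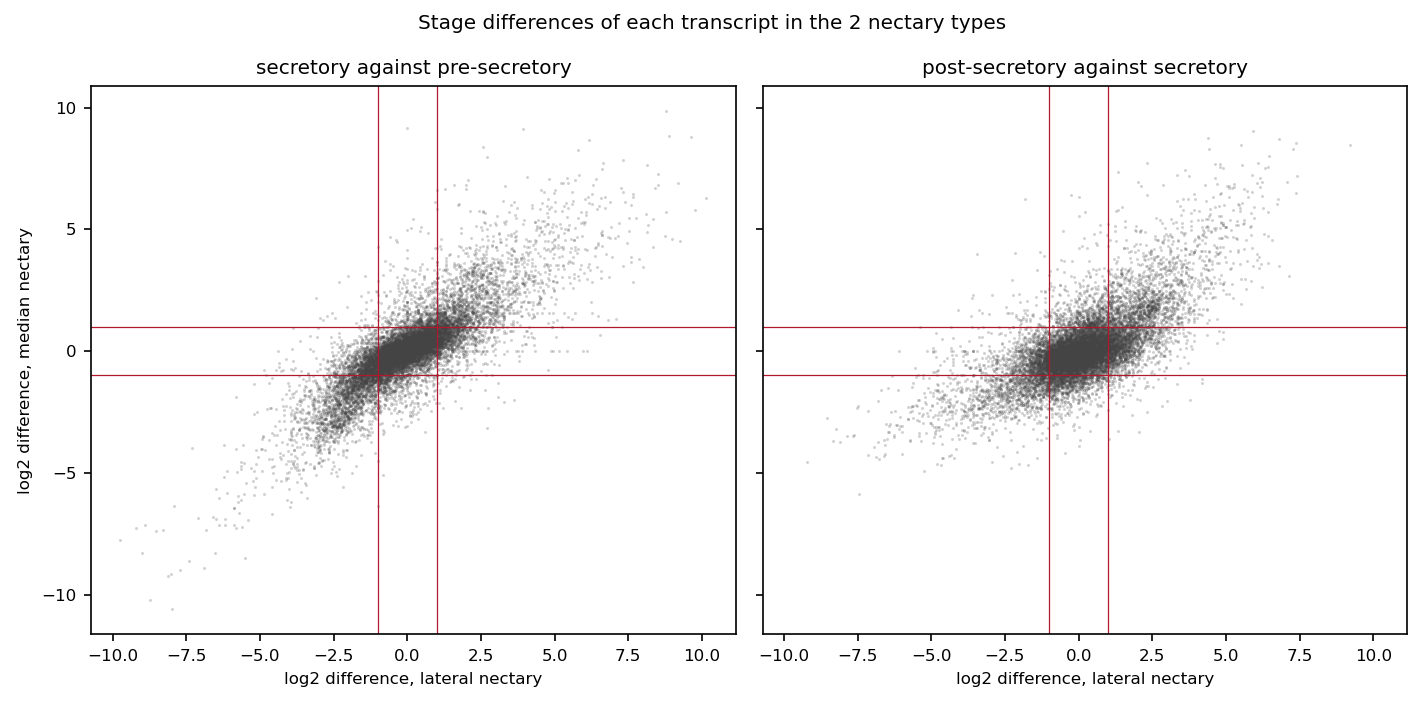
Log2 difference of each of 14398 transcripts in lateral (horizontal axis) and median nectaries (vertical axis), secretory against pre-secretory on the left and post-secretory against secretory on the right, with lines at 2-fold. Pearson's r across the 14390 transcripts kept is 0.824 on the left and 0.701 on the right.

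Nectar transcripts were lower after secretion in both nectary types. In lateral post-secretory nectaries 14 of 19 nectary and nectar transcripts were at least 2-fold lower than at the secretory stage and 0 were higher (median −2.98, below all random lists). CWINV4 was 202-fold lower (730 against 147338), PIN6 90.7-fold (15 against 1450), SWEET9 22.3-fold (6606 against 147160), MYB21 19.2-fold, JMT 7.92-fold and CRC 4.90-fold, while the JMT copy LOC103829478 was 1.56-fold lower. Jasmonate transcripts were lower in 12 of 21 cases and higher in 2 (median −1.11, percentile 0.03, and −0.47 with columns scaled to the same total), with OPCL1 at 96339 and 315 and VSP1 at 177 and 1.

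Senescence transcripts were higher at the lateral post-secretory stage in 6 of 7 cases (median 2.07, percentile 99.7, and 3.49 with the most expressed copies). NAP was listed at 1 and 331, the cysteine protease SAG12 (LOC103853666) at 3 and 240 and the NAC factor ORE1 (LOC103863903) at 12 and 423. Starch synthesis transcripts were higher in 6 of 9 cases and lower in 0 (median 1.44, percentile 99.7), with SBE2.1 (LOC103867285) 8.58-fold and SS2 4.58-fold higher. Sugar transport and sucrose cleavage had 9 of 19 higher and 5 lower (median 0.96, percentile 98.8), with SWEET15 at 5 and 471 and SUS1 23.2-fold lower. Auxin transcripts were higher in 4 of 7 cases and lower in 1 (median 1.18, percentile 98.3), the exception being IAA19 (LOC103859627), 22.8-fold lower. Clock transcripts were lower in 7 of 13 cases (median −1.11, percentile 0.33), with PRR9 7.35-fold, CCA1 2.16-fold and LHY 1.59-fold lower, the other LHY copy at −1.47. CCA1 had −0.46 both after quantile normalization and with same-total scaling. With columns scaled to the same total the clock median was −0.46, the sugar median 1.60, or 2.40 with the most expressed copy per locus alone, and the auxin median 1.82. Per the labels this stage came 12 h after the secretory one, and whether the time of day at sampling differed with the stage is not settled by them.

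Stress-response transcripts were higher in 1 of 7 lateral cases and lower in 4 (median −1.73, or −1.09 with same-total scaling), ZAT10 (LOC103835375) being 10.4-fold higher and HSP17.6 11.6-fold lower. Pollen markers had 0 of 4 higher and 1 lower (0.35, or 1.00 with same-total scaling), photosynthesis 1 and 1 of 27 (−0.30), floral organ identity 1 and 5 of 11 (−0.46), starch breakdown 7 and 3 of 14 (0.60, percentile 94.5), cell division 2 and 1 of 7 (0.46), glucosinolates 0 and 2 of 4 (−0.72, or −1.16 after quantile normalization) and vascular markers 1 and 1 of 6 (0.06). The starch breakdown median was 1.46 with the most expressed copy per locus alone and 1.24 with same-total scaling, which put cell division at 1.1. GASA4 was 31.7-fold and TPS03 7.24-fold higher, and both KAT1 transcripts were lower. In all, 3445 transcripts were higher and 2652 lower in lateral post-secretory than in secretory nectaries, or 5757 and 1383 with columns scaled to the same total, where the overall median was 0.70 in place of 0.063. The largest differences upward, besides NAP, were in pectinesterase 17 (LOC103866866), at 2 and 1765, uncharacterized LOC103853255, at 1 and 339, purine permease 21 (LOC103860975), at 1 and 311, and the transporter NPF6.4-like (LOC103835064), at 1 and 278. Downward, besides OPCL1, they were in LOC103834478, at 8354 and 13, AIR1B, at 27894 and 74, a GDSL lipase (LOC103834690), at 9061 and 27, and the transporter NPF4.3 (LOC103838583), at 7602 and 27.

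In median post-secretory nectaries 13 of 19 nectary and nectar transcripts were lower than at the secretory stage and 1 was higher (median −1.64, below all random lists). PIN6 was 12.2-fold, CWINV4 11.1-fold, JMT 4.96-fold, CRC 4.58-fold, MYB21 2.90-fold and SWEET9 2.66-fold lower (8959 against 23865). SWEET9 had a log2 of −1.41, which was −0.82 after quantile normalization and −0.89 with same-total scaling, both under 2-fold, and its other transcript had −0.57. The other JMT copies had −0.11 and −0.58. The exception was SPS2F (LOC103874391), 2.82-fold higher. Senescence transcripts were higher in 6 of 7 cases with a median of 4.90, above all random lists. SAG12 was listed at 20 and 10991, ORE1 at 24 and 2773, NAP at 16 and 1522, and SGR1 (LOC103861346), a factor in chlorophyll breakdown, at 150 and 3165. Photosynthesis transcripts were lower in 13 of 27 cases and higher in 0 (median −1.0, percentile 1.31), a median that was −0.47 with columns scaled to the same total and −0.83 after quantile normalization.

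Sugar transport and sucrose cleavage had 7 of 19 median transcripts higher and 5 lower (0.51, percentile 96.5, and 1.04 with same-total scaling), with SUS3 (LOC103836763) at 0 and 207, SWEET15 27.9-fold higher and SWEET10 (LOC103857270) 12.7-fold lower. Pollen markers were higher in 3 of 4 cases (median 1.04, percentile 98.0), VGD1 by 2.09-fold and AGP6 by 2.02-fold. Stress-response transcripts were higher in 1 of 7 and lower in 4 (median −1.08, percentile 0.29), and cell division in 0 and 2 of 7 (−0.85, percentile 1.51). Same-total scaling gave these 2 lists −0.56 and −0.33, and cell division had −1.2 by locus alone. Jasmonate had 4 higher and 7 lower of 21 (−0.18), with LOX2 19.0-fold lower, starch synthesis 2 and 3 of 9 (−0.22), starch breakdown 3 and 2 of 14 (0.29), floral organ identity 1 and 2 of 11 (−0.35), auxin 1 and 1 of 7 (0.25), glucosinolates 2 and 0 of 4 (0.76, or 0.11 with a pseudocount of 10 and 1.08 with same-total scaling) and vascular markers 0 and 2 of 6 (−0.24, or −2.00 by locus alone). Clock transcripts were lower in 3 of 13 cases (−0.42, percentile 17.7), with CCA1 1.1-fold and LHY 1.34-fold lower. GASA4 was 12.6-fold higher, TPS03 1.64-fold higher and KAT1 4.07-fold lower.

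In all, 2515 transcripts were higher and 2157 lower in median post-secretory than in median secretory nectaries, or 4048 and 1063 with columns scaled to the same total, where the overall median was 0.461 in place of −0.052. Besides SAG12, the largest differences upward were in a hevein-like protein (LOC103859057), at 2 and 1241, pectinesterase 17, at 25 and 9142, methylesterase 4-like (LOC103864478), at 2 and 1047, and cytochrome P450 81F1-like (LOC103860541), at 9 and 3161. Downward, they were in a transmembrane protein (LOC103861742), at 174 and 2, a Kunitz protease inhibitor (LOC103831736), at 6545 and 215, MLP-like protein 423 (LOC103829234), at 283 and 10, and a pair of transcripts matched to organelle genes, ATP synthase subunit alpha (LOC103848784), at 4747 and 169, and mitochondrial ribosomal protein L2 (LOC103833201), at 379 and 14. Across the 2 nectary types 1746 transcripts were higher in both after secretion, against 602.1 if independent, 1243 were lower in both, against 397.5, and 157 differed in opposite directions.

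**Figure D3:**
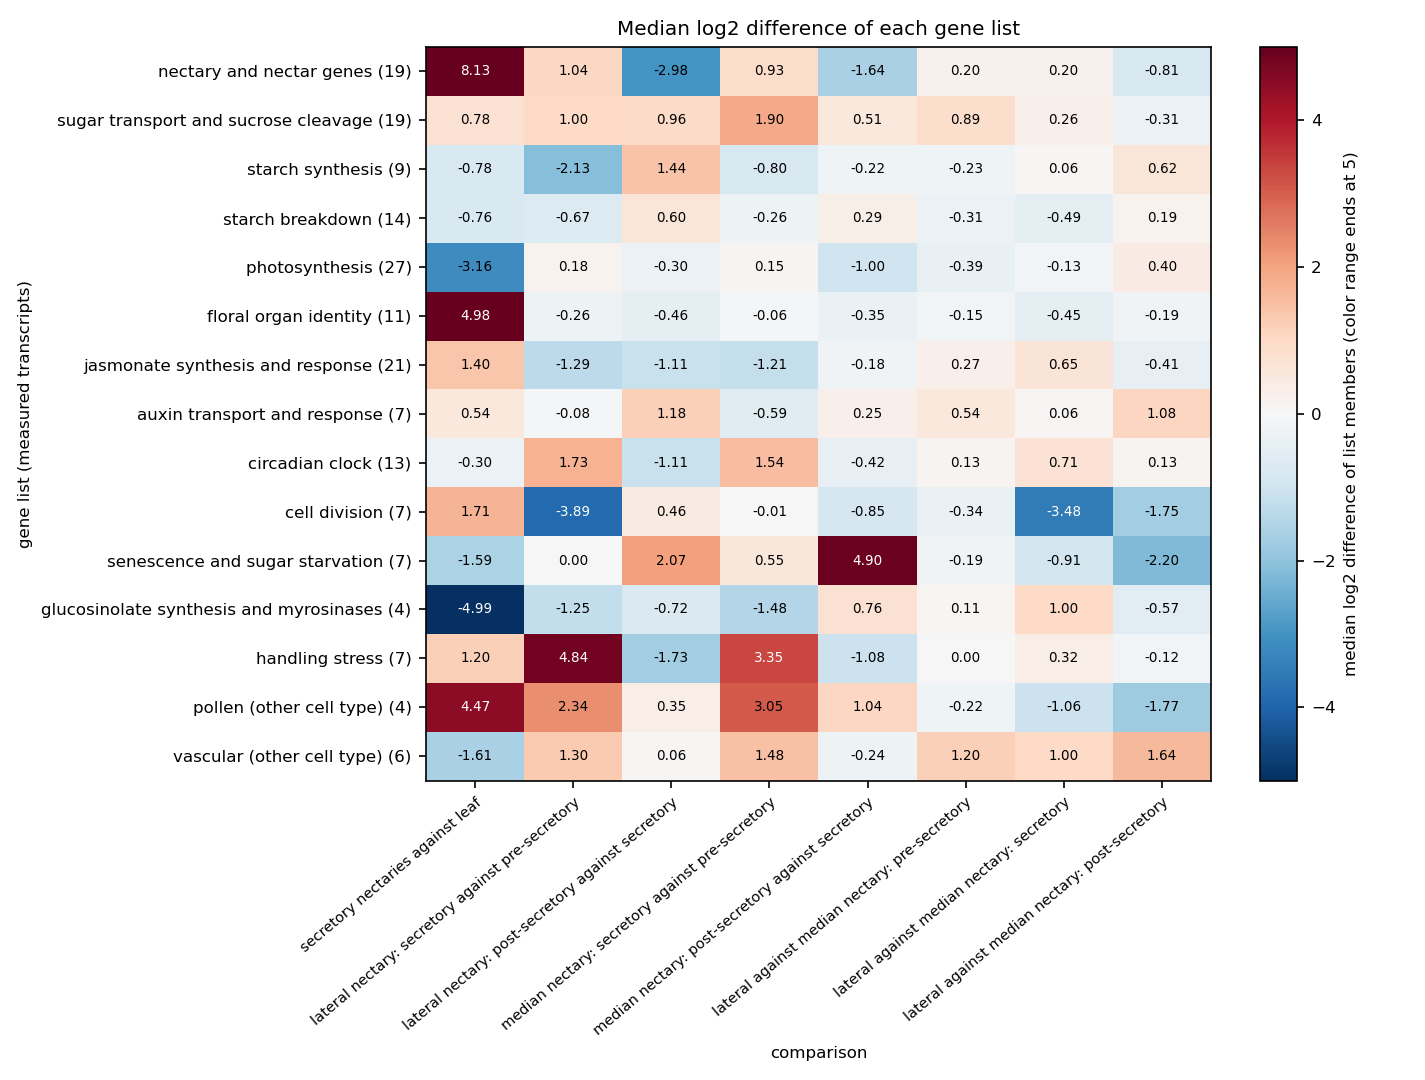
Median log2 difference of the gene lists with at least 3 measured transcripts (rows, number measured in brackets) in 8 comparisons (columns), red for higher and blue for lower in the first-named group. The nectary and nectar genes stand at 8.13 against leaf and at −2.98 and −1.64 after secretion, and the senescence list at 4.90 in median nectaries after secretion.

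Lateral and median nectaries were compared at each stage to find what separates a nectary type known to secrete most of the nectar in this family from one that secretes little. SWEET9 was 8.67-fold higher in lateral than in median nectaries before secretion and 6.17-fold higher at secretion, and 1.36-fold lower after it. PIN6 was lower in lateral nectaries at every stage, 297-, 18.0- and 134-fold (32 against 9790, 1450 against 26085 and 15 against 2138). CWINV4 was 3.13-fold higher before secretion, 1.89-fold higher at secretion and 9.61-fold lower after it. CRC and the JMT copy with the largest mean lay within 2-fold between types at all 3 stages, with log2 differences from −0.40 to 0.12 and from −0.81 to 0.23. The JMT copy LOC103829478 had −1.28 before secretion and −1.01 after it. MYB21 was 1.15-fold and 2.54-fold higher before and at secretion and 2.61-fold lower after it, its other copy 1.61-fold lower.

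Before secretion the nectary and nectar list had 6 of 19 higher in lateral nectaries and 5 lower (median 0.20, percentile 98.8, and 0.41 after quantile normalization). Sugar transport and sucrose cleavage had 9 of 19 higher and 3 lower (median 0.89, above all random lists, and 0.48 after quantile normalization), with SUC2 5.27-fold and SWEET5 5.92-fold higher and SWEET1 (LOC103835747) 250-fold lower (28 against 7257). Auxin had 3 of 7 higher and 0 lower (0.54, percentile 99.7), with PIN3 5.0-fold and IAA19 3.94-fold higher, jasmonate 2 and 0 of 21 (0.27, percentile 99.8) and photosynthesis 0 and 3 of 27 (−0.39, percentile 0.05). Starch breakdown had 0 higher and 2 lower of 14 (−0.31, percentile 0.52), and starch synthesis 1 and 2 of 9 (−0.23). Floral organ identity had 0 and 2 of 11 (−0.15), clock 0 and 0 of 13 (0.13), cell division 0 and 0 of 7 (−0.34), senescence 0 and 1 of 7 (−0.19), glucosinolates 0 and 0 of 4 (0.11), stress response 1 and 1 of 7 (0.00), and pollen markers 0 and 1 of 4 (−0.22). The vascular list had 3 higher and 0 lower of 6 (1.2, percentile 99.8). A transcript labelled APL here (LOC103849708), the symbol of a phloem factor, was 15.6-fold higher. However, 3 members of this list are assigned by product name alone. The list median was −0.34 with members taken by locus alone, 0.34 with a pseudocount of 10 and 2.40 with the most expressed copy per locus alone.

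In all, 1137 transcripts were higher and 636 lower in lateral than in median pre-secretory nectaries, the fewest of the comparisons made. The largest differences upward were in LIGHT-DEPENDENT SHORT HYPOCOTYLS 4 (LOC103828755), at 3976 against 33, the receptor kinase BAM3 (LOC103861192), at 2156 against 21, a gamma-glutamylcyclotransferase (LOC103870881), at 166 against 1, CML26 (LOC103831838), at 78 against 0, and the DIVARICATA factor (LOC103846919), at 61 against 0. Besides PIN6, the largest downward were in a cysteine-rich transmembrane protein (LOC103834697), at 0 against 331, branched-chain aminotransferase 7 (LOC103832898), at 39 against 11727, NPF7.3-like (LOC103840161), at 4 against 1450, and an epithiospecifier protein-like transcript (LOC103871086), at 3 against 1135.

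At the secretory stage cell division transcripts were lower in lateral nectaries in 5 of 7 cases and higher in 1 (median −3.48, below all random lists, and −1.53 by locus alone). MCM2 was 34.0-fold, MCM5 23.7-fold and MCM7 11.1-fold lower, and CDKB2;1 5.61-fold higher. Jasmonate had 5 of 21 higher and 3 lower (0.65, percentile 99.8), with OPR3 5.04-fold higher, and clock 3 and 2 of 13 (0.71, percentile 99.5), with LUX (LOC103873296) 4.46-fold and CCA1 2.77-fold higher. The sugar list had 9 and 7 of 19 (0.26, or 1.00 by locus alone), with SUC2 8.77-fold higher and SWEET15 44.2-fold and SWEET1 118-fold lower. Nectary and nectar genes had 7 and 4 of 19 (0.20), starch synthesis 0 and 3 of 9 (0.06), starch breakdown 5 and 4 of 14 (−0.49), photosynthesis 0 and 4 of 27 (−0.13), floral organ identity 1 and 2 of 11 (−0.45) and auxin 3 and 0 of 7 (0.06), with IAA19 22.5-fold higher. Senescence had 0 and 2 of 7 (−0.91, percentile 2.32), glucosinolates 3 and 1 of 4 (1.00, percentile 93.2, and 0.46 with a pseudocount of 10) and stress response 3 and 0 of 7 (0.32). Pollen markers were lower in 3 of 4 cases (median −1.06, percentile 0.87), AGP6 by 2.27-fold. Vascular markers had 3 higher of 6 (1.00), a median of −0.59 with members taken by locus alone, 0.51 with a pseudocount of 10 and 3.13 with the most expressed copies.

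At this stage 2115 transcripts were higher and 1863 lower in lateral nectaries. The largest differences upward were in uncharacterized LOC103840450, at 136 against 0, callose synthase 8 (LOC103870013), at 30942 against 354, the RING finger protein ATL5 (LOC103842073), at 4386 against 51, uncharacterized LOC103867674, at 70 against 0, and a receptor-like kinase (LOC103828924), at 64 against 0. Besides LOC103834697, at 16 against 5126, and aminotransferase 7, at 96 against 22667, the largest downward were in the epithiospecifier-like transcript, at 1 against 8340, the lipid transfer protein EARLI 1 (LOC103839886), at 5 against 2978, and pectinesterase 16 (LOC103866037), at 1 against 488.

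After secretion, senescence transcripts were lower in lateral than in median nectaries in 6 of 7 cases (median −2.20, below all random lists), with SAG12 at 240 against 10991, ORE1 at 423 against 2773 and SGR1 at 465 against 3165. Nectary and nectar transcripts were lower in 8 of 19 cases and higher in 1 (median −0.81, percentile 0.01), cell division in 4 and 0 of 7 (−1.75, or −0.67 by locus alone) and pollen markers in 4 and 0 of 4 (−1.77). Jasmonate had 3 of 21 higher and 6 lower (−0.41, percentile 0.11, and −0.27 with same-total scaling), with OPCL1 41.5-fold lower, auxin 4 and 0 of 7 (1.08, percentile 99.9), starch synthesis 2 and 0 of 9 (0.62, percentile 98.3) and photosynthesis 2 and 1 of 27 (0.40, percentile 99.6, and 0.77 after quantile normalization). For the sugar list the split was 4 and 5 of 19 (−0.31, percentile 1.72, and −0.17 with same-total scaling or −0.61 by locus alone), starch breakdown 4 and 0 of 14 (0.19), floral organ identity 0 and 2 of 11 (−0.19), clock 0 and 1 of 13 (0.13), glucosinolates 0 and 1 of 4 (−0.57), stress response 2 and 0 of 7 (−0.12) and vascular markers 3 and 0 of 6 (1.64), the last 0.33 by locus alone, 0.98 with a pseudocount of 10 and 3.14 with the most expressed copies.

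In all, 1820 transcripts were higher and 1354 lower in lateral than in median post-secretory nectaries. The largest differences upward were in BEL1-like homeodomain protein 11 (LOC103831995), at 94 against 0, PRR37 (LOC103851530), at 257 against 7, callose-binding protein 4 (LOC103829185), at 343 against 10, an auxin-repressed protein (LOC103867506), at 340 against 10, and the BAM3 kinase, at 322 against 10. Downward, they were in aminotransferase 7, at 6 against 3449, LOC103834697, at 2 against 1138, a germin-like protein (LOC103830683), at 139 against 41360, the GDSL lipase LOC103834690, at 27 against 7101, and the epithiospecifier-like transcript, at 6 against 1358.

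Averaged over the 3 stages, 1102 transcripts were higher and 815 lower in lateral nectaries. SWEET9 was 3.40-fold higher, SUC2 7.42-fold and IAA19 6.71-fold, and PIN6 89.3-fold and SWEET1 54.9-fold lower. CRC (log2 −0.19), CWINV4 (−0.23), MYB21 (0.05) and JMT (−0.24) lay within 2-fold. Cell division was lower in 5 of 7 cases (median −1.91, or −0.80 by locus alone), senescence in 4 of 7 (−1.10, percentile 0.02) and pollen markers in 2 of 4 (−1.02, percentile 0.08, and −0.94 with same-total scaling), and none of these 3 lists had a higher member (0 each). Auxin was higher in 3 of 7 cases (0.46, percentile 98.1) and vascular markers in 3 of 6 (1.33, or −0.46 by locus alone, 0.59 with a pseudocount of 10 and 2.89 with the most expressed copies). The other 10 lists with a percentile had medians from −0.26 to 0.23, within the range of 95% of random lists. The largest averaged differences were upward in the BAM3 kinase, 43.7-fold, a WAT1-related protein (LOC103836840), an APL-like MYB factor (LOC103845853), an ankyrin repeat protein (LOC103871523) and LOC103846532, and downward in the epithiospecifier-like transcript, 613-fold, LOC103834697, aminotransferase 7, the germin-like protein and PIN6.

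The difference between the stage differences of the 2 nectary types was computed for each transcript, lateral minus median. From pre-secretory to secretory stage it was at least 1 on the log2 scale for 1568 transcripts and at most −1 for 1578. PIN6 had 4.04 and MYB57 3.83, while SWEET9 (−0.49), CWINV4 (−0.73), CRC (−0.42) and JMT (−0.37) lay within 2-fold, and the CWINV4 copy LOC103857608 had −1.28. MYB21 had 1.14, its other copy 1.74 and CCA1 1.16. LHY had −0.43 and its other copy 1.37. After quantile normalization SWEET9, CWINV4 and CRC had −1.30, −2.44 and −1.22, the CWINV4 value carrying the replacement of the lateral pre-secretory maximum described above. Cell division had a median of −3.13 (−1.34 by locus alone) with 5 of 7 members at −1 or less, MCM2 at −4.38 and CDKB2;1 at 2.74. Sugar transport and sucrose cleavage had a median of −0.65 with 9 of 19 at −1 or less (percentile 0.29), jasmonate 0.45 (percentile 99.1), these 2 being −1.02 and 0.26 after quantile normalization, and pollen markers −0.89 (percentile 1.12, and −1.14 with the most expressed copies). The other 11 lists lay within the range of 95% of random lists, though 7 in place of 4 lists lay outside it after quantile normalization. The largest positive values were in LOC103840450, LOC103856730, the kinase LOC103828924, ABC transporter G19 (LOC103863189) and CMSS1 (LOC103866696), several of them listed at 0 in a group, so no values are given. The largest negative ones were in EARLI 1, pectinesterase 16, IAA26 (LOC103869753), a caffeoylshikimate esterase-like transcript (LOC103857865) and CML41 (LOC103860666).

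From secretory to post-secretory stage the difference was at least 1 for 2484 transcripts and at most −1 for 2207. Nectary and nectar genes had a median of −1.56 (−0.95 with the most expressed copy per locus alone) with 11 of 19 members at −1 or less and 0 at 1 or more, below all random lists. CWINV4 had −4.18, SWEET9 −3.06, PIN6 −2.89 and MYB21 −2.73. CRC (−0.10) and JMT (−0.67) lay within 2-fold, and the other JMT copies had −0.54 and −1.56. Jasmonate had a median of −1.12 (−0.86 with a pseudocount of 10) with 11 of 21 at −1 or less, OPCL1 at −5.04, and senescence −1.77 with 5 of 7 (percentile 0.06), SAG12 at −3.12. Positive medians were found for photosynthesis (0.67, 8 of 27 at 1 or more, percentile 99.9, and 1.12 after quantile normalization), cell division (1.56, percentile 99.7, and 0.46 by locus alone) and starch synthesis (0.94, percentile 99.1, and 1.13 after quantile normalization), and the glucosinolate list had −1.57 (percentile 1.3, and −0.71 with a pseudocount of 10 or −2.52 with one of 0.1). The largest positive values were in BEL1-like 11, RD22 (LOC103874419), oligopeptide transporter 3 (LOC103849516), mediator-associated protein 3 (LOC103849695) and the protease SBT5.3 (LOC103839651, 5.09). The largest negative ones were in an HVA22-like protein (LOC103832016), TAT4 (LOC103841973), amino acid permease 2 (LOC103855814), a WAT1-related transcript (LOC103854493) and CSLB3 (LOC103865205).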

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

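Each of the tests below was chosen after the list values had been seen, and the requirement of a value of at least 10 was added after the search without it had named a transcript near 0.

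Among 178 transcripts on the gene lists, 2 differed by 2-fold or more in opposite directions in lateral and median nectaries over the same stage step. The sugar transporter SWEET12 (LOC103874235) was lower at the secretory than at the pre-secretory stage in lateral nectaries, 1 against 7 (log2 −2.00), and higher in median nectaries, 33 against 3 (3.09), a difference of −5.09 between the types. The myrosinase TGG1 (LOC103834655) was lower at the post-secretory than at the secretory stage in lateral nectaries, 20 against 56 (−1.44), and higher in median nectaries, 74 against 19 (1.91), a difference of −3.35. Both differences between nectary types were not tested, since there is 1 value per group, and all 8 values are small beside the column medians, which run from 168 to 192. Without the requirement of a value of at least 10 there were 3, the other being SUS3 (LOC103836763), which was listed at 0 and 1 in lateral and at 1 and 0 in median nectaries.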

How the results depend on the processing

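Scaling to the same total, the pseudocount of 10, the filter at 50, 1 transcript per gene and locus-only members were tests chosen after the results were seen. Of the 11 counts of transcripts past 2-fold, each stayed within 1.5 times its reported size under every alternative run for it. The count for the interaction from pre-secretory to secretory stage ranged from 2409 to 3301, and that of secretory nectaries against leaf from 6834 to 7556. The split between higher and lower did depend on scaling: with columns scaled to the same total, 28.4% of the transcripts past 2-fold were higher in lateral secretory than in pre-secretory nectaries, against 47.7% as reported, and 80.6% against 56.5% in the next step. Quantile normalization gave 7 lists outside the range of 95% of random lists for the interaction from pre-secretory to secretory stage, in place of 4, and the cause was not tested. Taking list members by locus only reversed the vascular median for secretory nectaries against leaf (from −1.61 to 2.12) and for lateral against median nectaries before secretion (1.2 to −0.34), at secretion (1.00 to −0.59) and averaged over stages (1.33 to −0.46), because 3 of its 6 members are assigned by product name alone. Of 165 list medians, 21 crossed 2-fold, in or out, under same-total scaling, 11 under quantile normalization, 12 with a pseudocount of 10, 11 of 154 with the most expressed copy only, 9 more by locus only, 1 each with a pseudocount of 0.1 and with 1 transcript per gene, and 0 with either filter. Among the 89 list medians of 0.75 or more in size or outside the range of 95% of random lists, 45 moved by over 1.5 times under at least 1 alternative. The nectary and nectar list in lateral secretory against pre-secretory nectaries had 1.04 as reported, 0.30 after quantile normalization and 0.55 with same-total scaling. Over all comparisons CRC, SWEET9, CWINV4, MYB21, PIN6, JMT, CCA1 and LHY had 88 values. Of these, 13 moved under quantile normalization and 6 under same-total scaling. Among them were CRC, JMT and MYB21 over that step (−0.69 to −1.76, −0.95 to −1.91 and 1.12 to 0.30 after quantile normalization) and SWEET9 in median nectaries after secretion (−1.41 to −0.82). The cause was not tested. No paired analysis was possible because the values are 1 per group and not per replicate. For the same reason leave-one-out runs, other count models with their normalizations and count filters, a replicate block, fits of only the groups compared, options of set tests and other adjusted p thresholds were not run. Depth per library is unknown, so no limit for weakly expressed transcripts is given beyond the 48 to 163 transcripts per column listed at 0.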

Other observations

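Of the tests below, those of column scaling, of organelle RNA and of spans of at most 600 bases were chosen after the results were seen, as were the families, looked at in 2 passes of 25 and then 20 product-name families. An earlier test of scaling, by the median of all transcripts, was dropped: the authors had normalized the columns, whose medians run from 168 to 192, so it decides nothing. The later tests by 2 other scalings could hardly have come out otherwise. Over the step to secretion, same-total scaling moved the median of all transcripts only to −0.53 (lateral) and −0.37 (median). Each pattern below was larger than that. Cytosolic ribosomal protein transcripts, 248 in all, had a median log2 difference of −2.18 in lateral and −2.78 in median nectaries from the pre-secretory to the secretory stage, with 232 and 234 members at least 2-fold lower. They were higher after secretion (2.37 and 1.71), a step that shares the secretory value with the first. Ribosomal proteins of organelles, 76 in all, were lower at secretion as well (−2.54 and −2.30). Core and linker histones, which package new DNA, had −2.03 in lateral and −0.88 in median nectaries, 40 and 20 of 51 being lower, and the latter median was −1.29 with same-total scaling. Small heat shock proteins, chaperones of unfolded proteins, had 5.27 and 5.77 at secretion and −3.58 and −3.62 after it (13 measured). Again both steps share the secretory value. At secretion 12 were higher and 1 lower in lateral nectaries, and 11 higher and 0 lower in median ones. The lower one, LOC103851948, was listed at 555 and 208 in lateral nectaries. Several others were listed at 0 or 1 before secretion, so the pseudocount sets part of the size of these medians. HSP17.6 of the stress-response list is among the small heat shock proteins. Other heat shock transcripts went both ways at secretion. Heat shock 70 kDa protein 8 (LOC103867668) had 3.48 and 1.82, and a heat shock protein 90-1-like transcript (LOC103875375) had −2.19 and −1.93. NAC transcription factors (40 measured) had 25 and 30 members higher at secretion and 0 lower, and WRKY factors (33 measured) 19 higher in each type and 0 lower, although the lateral WRKY median of 1.04 was 0.56 with same-total scaling. Signs of these medians were the same under quantile normalization and same-total scaling.

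NRT1/PTR transporters, which carry nitrate, peptides and hormones, had 16 of 26 members higher and 4 lower at secretion in lateral nectaries (median 1.47) and 15 higher and 1 lower in median nectaries (1.14), medians of 0.98 and 0.73 with same-total scaling. Aquaporins, 24 measured, were more often higher than lower after secretion, with 13 higher and 5 lower in lateral (median 1.14) and 14 higher and 4 lower in median nectaries (1.40), medians of 1.77 and 1.90 with same-total scaling, which raises most transcripts in this step. Myrosinase-binding proteins were lower at secretion in 9 of 10 lateral and 8 of 10 median cases (−5.22 and −4.03). Callose synthases were higher in lateral than in median secretory nectaries in 8 of 13 cases and lower in 1 (median 1.24, or 0.93 after quantile normalization). The F-box/kelch transcript LOC103828338, which has no Arabidopsis match, was listed at 1477508 in median secretory nectaries and from 16590 to 190392 in the other 6 groups.

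Pollen markers were higher in secretory and post-secretory nectaries than before. If pollen RNA were the source, pollen transcripts would keep their proportions, and over 4 transcripts at pollen loci whose values had not been seen, the SD of the log2 ratio of post-secretory to secretory median nectaries was 0.08, where random sets had a median of 0.94. Among the 4, LOC103859515 and LOC103870173 match the same locus, which the random sets did not imitate. Transcripts that vary together within nectary cells would also keep their proportions, so the ratio does not single out pollen RNA. Quantile normalization and same-total scaling did not remove the pattern. Under both, the median of the 4 listed markers from pre-secretory to secretory stage was 1.85 or more in both types, above matched random lists. RNA from pollen may thus account for these transcripts, although ACA9, at 2747 and 2408, departs from the other markers, and they are not at 0 in leaf, where VGD1 is listed at 81. Expression by nectary cells themselves was not tested and stays open.

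Of 8 transcripts matched to organelle genes, 6 were highest in median secretory nectaries and over 2-fold higher there than before secretion: LOC103833954 was listed at 276, 26995 and 1152 over the 3 stages and LOC103848419, cytochrome b, at 205, 14301 and 569. Medians of this difference were 6.12 for the 3 matched to the chloroplast and 5.17 for the 5 matched to the mitochondrion, while nuclear photosynthesis transcripts had 0.15. The other 2 scalings did not remove this difference, the median of the 8 being 5.03 or more under them. Organelle RNA carried into the libraries and a difference in organelle transcription cannot be told apart: LOC103853621 was lower at secretion (−5.36), LOC103853804 differed by less than 2-fold (0.12), the latter and LOC103836843 also match nuclear loci, and whether any of the 8 are copies in the nuclear genome is not known. No biological explanation was tested.

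Cytosolic ribosomal protein transcripts were lower in secretory nectaries of both types. Other transcripts matched on mean value and span had a median of 0.17 in the type where it was lower, against −2.78 for the ribosomal proteins. A span includes introns, and only 151 of 248 were compared by it. Other transcripts whose match spans at most 600 bases had a median of 0.20 in the type where it was lower when drawn to the mean values of the family. Transcripts of short span were thus not lower as a set. Whether the spans hold untranslated regions is not known, so they do not bound transcript length, and loss of short transcripts is not settled. The other 2 scalings did not remove the pattern, the family median nearest to 0 over them and both types being −2.16. No biological explanation was tested, and cell composition, time of day, handling and the authors' processing were not tested.

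These are 3 of 4 patterns tested. The 1 set aside, after its outcome was seen, was that clock genes differed between pre-secretory and secretory nectaries: 6 of 6 morning-phased transcripts were over 2-fold higher in both nectary types, and 0 of 4 evening-phased ones were over 2-fold lower in both, with differences from −1.43 to 0.71. Time of day at sampling was not resolved by these values.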
